A study of Mus musculus with 12 samples.

How the data were processed

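The series measured polyadenylated RNA of mouse heart cells in 12 libraries made with a stranded mRNA kit, per the labels' protocols. The samples fall into 6 groups of 2 by their titles: fresh Thy1-sorted fibroblasts, fresh cardiomyocytes, and fibroblasts at day 3 with control retrovirus, MGT retrovirus, MGT with a non-targeting hairpin or MGT with a Ptbp1 hairpin. The titles of the control group name lacZ whereas other labels name an empty vector, so the group is called control vector here. One library of the Ptbp1 hairpin group has a source label that names Ptbp2, and its group was taken from its title and the treatment label.

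The authors deposited 1 table of CPM for 23423 genes, 1 column per library, and all 12 columns were matched to samples by name. The reads were handled with FastQC, TopHat2 2.1.0 and HTSeq 0.6.1p1 on the mm10 build, per the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty, and close gene copies may share or lose reads. Each CPM column summed to 1000000, so the deposited CPM carry no scaling factor beyond depth. The values were whole multiples of 1 read per library within a tolerance of 0.1 reads for 100% of values, which gave back the whole reads and a depth of 49320858 to 94005212 assigned reads per library. At this depth 1 read was worth 0.0106 to 0.0203 CPM. In 27 rows the gene name had been turned into a number, as spreadsheets do with date-like names; these rows stayed in the tests and were not named. The 3 globin genes in the table are listed at 0 in every library, and nothing is read from that.

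For the tests the CPM were divided by a median-of-ratios factor per library (0.966 to 1.06), and genes with at least 1 CPM in at least 2 libraries were kept, 13977 in all. Log2(scaled CPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, 6 residual degrees of freedom and eBayes with trend. The tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 5 comparisons were cardiomyocytes against fibroblasts, MGT against control, shPtbp1 against shNT, shNT against MGT alone, and control cultures against fresh fibroblasts. A rank or permutation test of 2 against 2 libraries cannot go below p = 0.333, so no such test was run.

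In all, 22 lists of genes by function and 7 lists of cell type markers were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, where at least 5 members were tested, which left 27 lists. The setting with an estimated correlation also raised the adjusted p of called lists whose estimate lay below 0.01. A call lost in that setting is therefore not by itself an effect of correlation between genes. Sets of 200 genes each way were taken from the calls of cardiomyocytes against fibroblasts with at least 10 scaled CPM in the higher group, leaving out the delivered factors and Ptbp1. The genes named in the text follow a rule: in the first 3 comparisons the 10 largest increases and the 10 largest decreases among calls with at least 10 scaled CPM in the higher group and no overlap of replicates, and 5 each way in the other 2. Predicted and unnamed genes were not named, and 1 gene is not reported here. Ptbp1, Ptbp2, Mef2c, Gata4 and Tbx5 were always named, and of each list up to 4 members with the largest change. The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined. Gene positions come from GENCODE annotation of GRCm38, which is the mm10 build, 1-based.

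The procedure was tested on simulated data in which 50 genes were changed at each size and the other genes did not differ between the 2 groups compared. Genes were drawn independently of each other. The data had far more calls and may hold effects shared by many genes, so these rates need not hold there. For MGT against control, 54% of genes changed by 0.25 log2 units were recovered, 94% at 0.5 and 100% at 1, among 13919 genes, and 3.87% of calls were false. For shPtbp1 against shNT 54%, 96% and 100% were recovered among 13916 genes, and 5.41% of calls were false. For cardiomyocytes against fibroblasts 58%, 94% and 100% were recovered among 13845 genes, and 7.37% of calls were false. In the other 2 comparisons 4.74% and 5.91% of calls were false.

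The alternatives were no further scaling, upper-quartile scaling, quantile normalization, pseudocounts of 0.1 and 2, no filter or a filter at 5 CPM, fits of only the 4 libraries compared or of the 8 day 3 libraries, a robust prior, the replicate number as a block, each replicate left out in turn, and edgeR 4.0.16 (quasi-likelihood test) on the recovered reads. For the lists an estimated correlation was tried, and for the cell type sets 100 and 500 genes each way. Figures were drawn with matplotlib 3.10.9. Splicing, isoforms and the single-cell part of the study were not analysed here.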

Results

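Polyadenylated RNA was sequenced from 12 libraries in 6 groups of 2. The starting cells came from hearts of CD1 mice at postnatal day 1.5. Freshly isolated cardiac fibroblasts had been purified by magnetic sorting on the surface protein Thy1, and freshly isolated cardiomyocytes came from a commercial neonatal preparation. The other 4 groups were cardiac fibroblasts put into culture and collected 3 days after viral transduction. They received a control retrovirus, a retrovirus carrying the cardiac transcription factors Mef2c, Gata4 and Tbx5 (MGT), MGT with a lentiviral non-targeting hairpin (shNT), or MGT with a lentiviral hairpin against Ptbp1 (shPtbp1). MGT is a factor combination used to convert fibroblasts directly into cardiomyocyte-like cells. The purpose given by the submitters was to provide bulk references for single-cell work and to study splicing after Ptbp1 depletion. The table analysed here holds gene levels without isoforms, so splicing itself was not analysed here.

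The libraries held 49320858 to 94005212 reads assigned to genes, and 13977 genes were tested. Values are given as scaled CPM (reads per 1000000 assigned reads, divided by a library factor), mean ± SD with n = 2. Fold changes are on the log2(scaled CPM + 0.5) scale with the standard error (SE), which understates the change of low genes. Replicates of a group differed with an SD of 0.113 to 0.145 in log2 units across genes. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these samples only, which may be technical. The first principal component held 82.2% of the variance and parted fresh from cultured cells. The second held 9.36% and parted cardiomyocytes from fibroblasts, and the third held 5.4% and parted the hairpin wells from the other cultured wells.

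Ptbp1 encodes the polypyrimidine tract binding protein 1, a repressor of many exons, and lies on chromosome 10 at 79854427 to 79864771 (GRCm38, plus strand). Its level was 489 ± 2.46 scaled CPM in fresh fibroblasts, 420 ± 1.26 in cardiomyocytes, 358 ± 4.8 in control cultures, 372 ± 11.2 with MGT and 362 ± 3.62 with MGT and shNT. With shPtbp1 it was 79.8 ± 1.85, and both replicates lay below every other library. Replicate 2 of that group names a hairpin against Ptbp2 in one of its labels. In that library Ptbp1 was low and Ptbp2 was high, as in replicate 1, and the title and the other labels name Ptbp1.

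**Figure D1:**
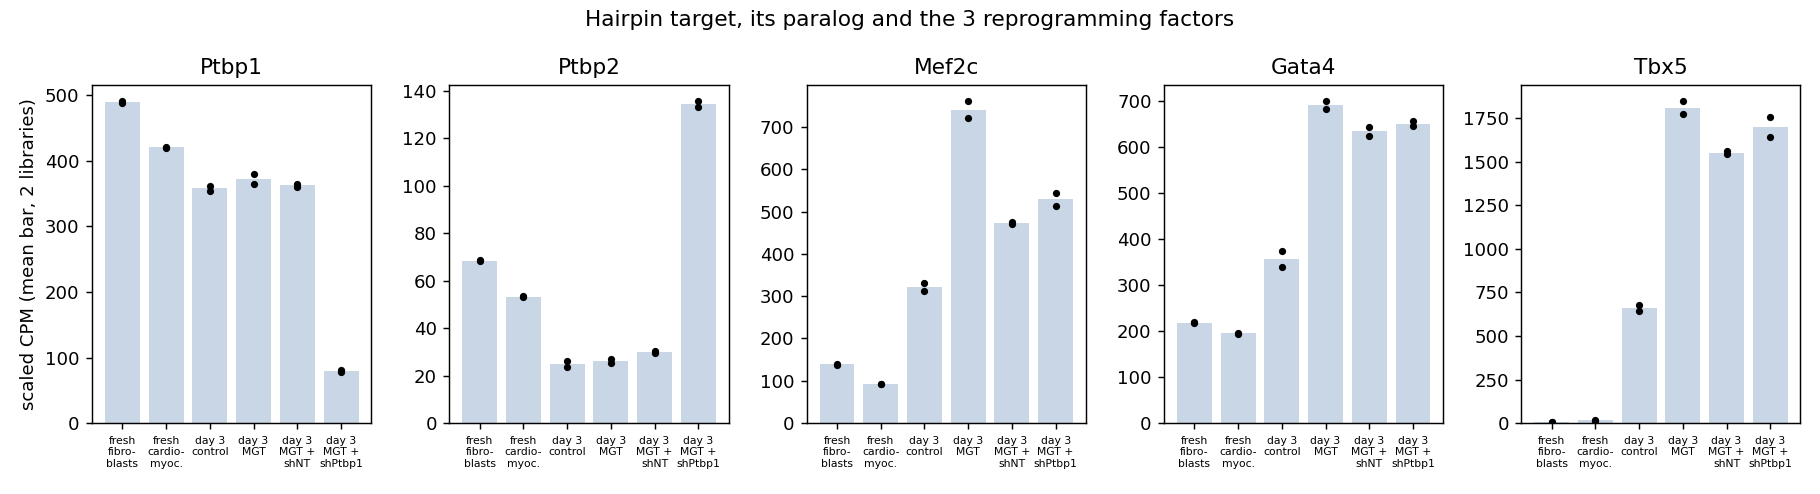
Scaled CPM (linear axis from 0) of Ptbp1, Ptbp2, Mef2c, Gata4 and Tbx5 in the 6 groups; bars are means and points the 2 libraries of each group. Ptbp1 was 79.8 in the shPtbp1 group against 362 in the shNT group, while Ptbp2 was 134 against 29.9.

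Cardiomyocytes and fibroblasts, the reference cell types of the series, differed first in muscle and energy genes. All 25 sarcomere genes were higher in cardiomyocytes, with a median log2 fold change of 3.17. Among them were the ventricular light chains Myl3 (1080 ± 19 against 72.8 ± 0.742) and Myl2 (3287 ± 143 against 245 ± 5.34), the titin cap Tcap and the slow troponin Tnni1. The genes with the largest increases were Xirp1, an actin-binding protein of the intercalated disc, at 20.3-fold (243.9 ± 1.98 against 11.5 ± 0.768), and the natriuretic peptide gene Nppb at 17.6-fold. They were followed by Xirp2, Cox8b, Smpx, Ppp1r3a, Myl3, Adprhl1, Tcap and Myl2, from 15.6-fold to 13.4-fold. Fibroblasts had the higher level of the extracellular protein multimerin Mmrn1 (42.9 ± 1.15 against 1.015 ± 0.0349), the proteoglycan aggrecan Acan (27.0 ± 0.115 against 2.79 ± 0.235) and the smooth muscle myosin Myh11 (162 ± 4.35 against 31.0 ± 0.485). The olfactory receptor Olfr78, reelin Reln, Serpina3n, endosialin Cd248, the potassium channel Kcnj15, C1qtnf7 and Pianp were also lower in cardiomyocytes, by -2.81, -2.45, -2.33, -2.15, -2.03, -1.95 and -1.95 in log2 units.

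Of 23 calcium handling and ion channel genes, 19 were higher in cardiomyocytes and 1 was lower, led by sarcolipin Sln, phospholamban Pln, the ryanodine receptor Ryr2 and triadin Trdn with log2 fold changes of 3.36, 3.29, 3.23 and 3.22. All 20 other cardiomyocyte markers were higher. Fatty acid oxidation genes were higher in 23 of 23, including Pdk4 (2.95), the coactivator Ppargc1a (2.86) and Acadl (2.47). These 4 lists were called by the camera test with adjusted p of 2.34e-18, 1.72e-08, 3.29e-15 and 1.31e-14, and held with an estimated correlation (adjusted p of 0.00864, 0.00864, 0.0177 and 0.0308). Oxidative phosphorylation rose in 30 of 30 genes, ribosomal proteins in 30 of 30 and glycolysis in 15 of 16, with adjusted p of 3.99e-19, 9.01e-12 and 1.02e-08. With an estimated correlation these 3 lists had adjusted p = 0.0853, 0.193 and 0.0508.

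On the fibroblast side, 28 of 32 extracellular matrix genes were lower in cardiomyocytes and 3 were higher. The elastic fibre genes Mfap4 and Loxl1 were lower by -1.48 and -1.37 in log2 units, whereas the matricellular gene Ctgf was higher in cardiomyocytes by 1.37. Of 19 fibroblast identity genes 14 were lower, including the collagen receptor Ddr2 and the growth factor receptors Pdgfrb and Pdgfra, with log2 fold changes of -1.40, -1.28 and -1.25. Higher in cardiomyocytes were 2 of the identity genes. Of 16 myofibroblast and smooth muscle contractile genes 13 were lower and 3 were higher. These lists had adjusted p of 7.21e-08, 0.000968 and 0.00044, and adjusted p = 0.185, 0.0602 and 0.196 with an estimated correlation. Markers of other cell types differed as well. Macrophage markers were lower in 10 of 14 and higher in 2 (adjusted p = 0.00664, and 0.0941 with an estimated correlation). Pericyte markers were lower in 5 of 6 (0.0469 and 0.173). Endothelial markers were higher in 9 of 14 and lower in 1 (0.025 and 0.326), with Vwf at 443 against 147 in the Thy1-sorted fibroblasts. The 3 erythroid markers tested, too few for a list test, were higher in cardiomyocytes (median 2.45), with Alas2 at 22.6 against 3.73 and Slc4a1 at 9.30 against 0.964. Of 5 lymphocyte markers 4 were higher and Cd4 was lower, with Cd79a at 6.12 against 1.42, without a list call (adjusted p = 0.0857, and 0.326 with an estimated correlation).

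Smaller lists completed the picture. Cardiac transcription factors were higher in 10 of 15 genes and lower in 2, with Ankrd1, Smyd1, Irx4 and Nkx2-5 highest at log2 fold changes of 3.32, 3.20, 3.07 and 2.87. The p53 and senescence list was higher in 11 of 17, led by Gdf15 (3.12) and Perp (3.01), and lower in 4. Inflammatory genes were higher in 12 of 19 and lower in 5, and mitosis genes were higher in 13 of 20 and lower in 3. Their adjusted p were 0.00144, 0.00966, 0.0283 and 0.0175, and 0.173, 0.193, 0.326 and 0.0941 with an estimated correlation. Of the factor genes, Tbx5 was higher in cardiomyocytes, by 1.03 in log2 units, and Mef2c was lower, by -0.57. Mef2c was 93.0 ± 0.235 in cardiomyocytes and 139 ± 0.811 in fibroblasts, Gata4 was 195 ± 1.03 and 219 ± 1.03, and Tbx5 was 15.25 ± 1.22 and 7.23 ± 0.415.

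Over all genes, 4925 were higher and 5830 lower in cardiomyocytes at an adjusted p below 0.05 by limma, of which 1154 and 559 changed at least 2-fold. Sarcomere transcripts were not confined to one preparation, since Tnni1 was 569 ± 24.8 in cardiomyocytes and 42.3 ± 3.62 in fibroblasts. Nor were fibroblast transcripts. The median matrix gene stood at 10.31 log2 units in both cardiomyocyte libraries, against 10.99 and 11 in fibroblasts. The fibroblast identity median was 5.52 and 5.53 against 6.15 and 6.16. These differences are therefore between 2 preparations, which may each hold other cells. Adjusted over the list alone, the counts were the same except for 11 cardiac transcription factors higher and 0 endothelial markers lower. The pericyte call was lost without cardiomyocyte replicate 2, without fibroblast replicate 2 and at a pseudocount of 0.1, and the 559 became 327 at a pseudocount of 2.

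MGT against the control retrovirus addressed the early response to the reprogramming factors. By day 3, 18 of 25 sarcomere genes were higher with MGT and 1 was lower, and 14 of 23 calcium handling and ion channel genes were higher with none lower. The giant sarcomere protein titin, Ttn, was 259 ± 12.7 against 88.7 ± 20.3, and myomesin Myom2 was 341 against 139. Cardiac troponin I, Tnni3, was 20.4 against 8.23, and cardiac actin Actc1 was 229 against 98.8. Sarcolipin Sln, triadin Trdn and calsequestrin Casq2 rose by 1.21, 0.94 and 0.91 in log2 units. Both lists were called by camera, with adjusted p of 7.17e-12 and 4.23e-08, and held with an estimated correlation (adjusted p = 0.0168 for both).

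The delivered factors were higher. Mef2c (chromosome 13, 83504034 to 83667080) was 741 ± 29 with MGT and 322 ± 12.3 in control. Gata4 (chromosome 14, 63198922 to 63271692) was 692 ± 12.6 and 358 ± 24.1, and Tbx5 (chromosome 5, 119832668 to 119885219) was 1809 ± 54.2 and 661 ± 23.2. Reads from the virus and from the endogenous genes cannot be parted at gene level. Tbx5 was only 7.23 ± 0.415 in fresh fibroblasts, so its level in control cultures was already high. Whether the control wells held factor transcripts from virus was not settled here, and if they did, the changes with MGT could be understated. Outside the factors, the largest increases were in the collagen gene Col10a1 (36.8 ± 0.673 against 5.91 ± 0.479), Ccdc3, the calcium-binding protein Necab1 and Abi3bp (401 ± 6.91 against 112 ± 1.19), with log2 fold changes of 2.54, 2.41, 2.21 and 1.84. The potassium channel Kcnc4, the kinase Wnk4, the natriuretic peptide protease Corin, myoglobin Mb, the metalloproteinase Mmp15 and Ttn followed, from 1.82 to 1.56. The largest decreases were in sphingomyelinase Smpd3, Lrrn4, osteoprotegerin Tnfrsf11b, Cyp1b1 and Kif26b, from -1.53 to -1.02. Dpep1, Pkhd1l1 and Ctla2a came next, at 35.3, 5.40 and 19.4 scaled CPM against 71.8, 11.2 and 37.9. The chemokine gene Ccl12 and the chemokine receptor gene Cx3cr1 fell by 0.96 and 0.92.

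Of 15 cardiac transcription factors on the list 6 rose and none fell, among them Esrrg (1.10), Smyd1 (0.83) and Myocd (0.55). Of 20 other cardiomyocyte markers 12 rose, including Mb (1.60), desmin Des (0.88) and the splicing factor Rbm24 (0.85). These 2 lists had adjusted p of 0.000998 and 1.53e-06, and 0.214 and 0.0922 with an estimated correlation. Extracellular matrix genes fell in 19 of 32 and rose in 3, with Mfap4, elastin Eln and fibulin Fbln2 lower by 0.84, 0.72 and 0.55 in log2 units. Inflammatory genes fell in 15 of 19, among them Saa3, Vcam1 and Ptgs2. Cell cycle lists fell too, DNA replication in 13 of 20 genes and mitosis in 11 of 20. Ribosomal protein genes fell in 23 of 30, Rps14 most, by 0.59. Markers of other cells also fell. Endothelial markers were lower in 8 of 14 and higher in 2, and epicardial markers lower in 6 of 9, with Krt8 lower by 1.25, and higher in 1. The epicardial median was 4.41 and 4.4 log2 units with MGT and 4.94 and 4.88 in control. It was 5.05 and 5.12 with MGT and shNT, and 4.93 and 4.86 with MGT and shPtbp1. Low values in the MGT libraries alone may add to this fall, although shNT against MGT had no epicardial camera call (adjusted p = 0.296). Macrophage markers fell in 6 of 14 and rose in 2, without a list call (adjusted p = 0.108).

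The matrix, inflammatory, DNA replication, mitosis, ribosomal, endothelial and epicardial lists had camera adjusted p of 7.04e-07, 2.58e-08, 0.000149, 0.000218, 3.9e-10, 0.000289 and 0.000614. Mitosis held with an estimated correlation (adjusted p = 0.043). The others had adjusted p = 0.263, 0.0763, 0.173, 0.263, 0.214 and 0.173 in that order. Over all genes, 2497 were higher and 2475 lower, and 108 and 15 changed at least 2-fold. The balance depended on the scaling, with 2214 higher and 2933 lower under upper-quartile scaling and 2350 and 2685 without scaling. Ptbp1 was 372 ± 11.2 with MGT and 358 ± 4.8 in control (adjusted p = 0.222), and Ptbp2 did not pass (0.234, with 0.0346 without control replicate 1). The lower count was 1598 without MGT replicate 2. The 2-fold counts were 202 and 73 with edgeR's quasi-likelihood test on recovered reads. Adjusted over the list alone, 14 DNA replication, 13 mitosis and 7 epicardial genes were lower and 2 cardiomyocyte markers were lower, and the other called lists kept their counts.

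The cardiomyocyte and fibroblast sets, the 200 genes each way with the largest fold change between the fresh cells, share no library with this comparison. With MGT, 90 cardiomyocyte genes rose and 22 fell, with a median log2 fold change of 0.215 (adjusted p = 2.47e-10, and 0.00838 with an estimated correlation). The mean of this set was 2.84 and 2.86 log2 units with MGT and 2.55 and 2.57 in control. That stayed below fresh fibroblasts, at 3.09 and 3.11, and cardiomyocytes, at 6.01 and 6.03. Of the fibroblast genes, 39 rose and 54 fell, without a call (median -0.05, adjusted p = 0.148). The fibroblast set mean was 4.14 and 4.17 with MGT and 4.17 and 4.19 in control. Fresh fibroblasts stood at 5.72 and 5.73 and fresh cardiomyocytes at 4.25 and 4.26. The set was thus already low in control cultures, so the missing call says little about a loss of fibroblast genes with MGT. Across all 13977 genes, which are not independent replicates, the MGT change and the cardiomyocyte-to-fibroblast difference had Pearson r = 0.053 and Spearman rho = -0.044. Of 4053 genes called in both, 43.9% had the same direction, with 830 higher in both where independent lists would give 880 and 949 lower in both where they would give 1032.

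**Figure D2:**
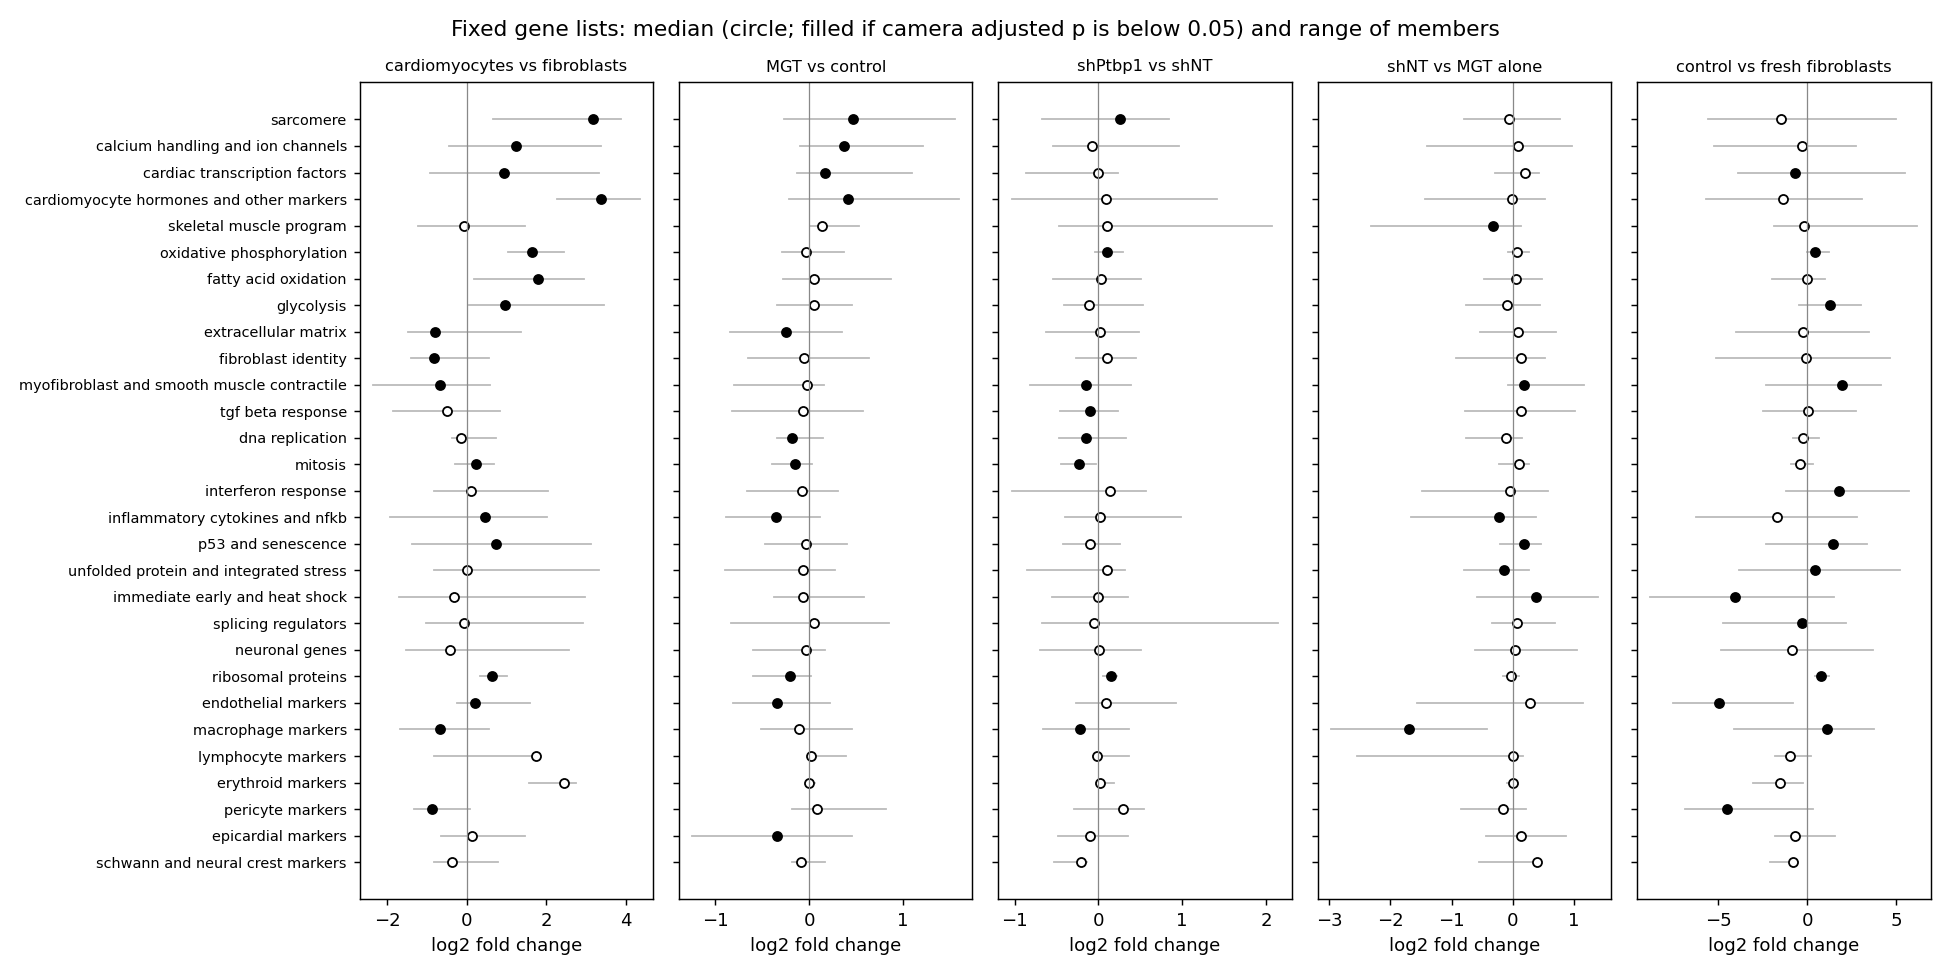
Median (circle) and range (line) of log2 fold changes of each fixed gene list in the 5 comparisons; filled circles mark lists with a camera adjusted p below 0.05 at the preset correlation. The sarcomere median was 3.17 for cardiomyocytes against fibroblasts, 0.47 for MGT and 0.26 for shPtbp1.

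Silencing Ptbp1 during reprogramming was compared between the shPtbp1 and shNT wells, both with MGT. Ptbp1 was 4.52-fold lower, at 79.8 ± 1.85 against 362 ± 3.62, with a log2 fold change of -2.18 ± 0.034 (limma adjusted p = 8.25e-19). Its neuronal paralog Ptbp2, on chromosome 3 at 119718742 to 119784466, was 134 ± 1.86 against 29.9 ± 0.726, a log2 fold change of 2.15 ± 0.049. Mitosis genes fell in 16 of 20 with none higher. Of 25 sarcomere genes 16 rose, 3 fell and 6 did not pass, and the list had adjusted p = 0.125 with an estimated correlation. The largest increase was in the muscle taxilin Txlnb (71.8 ± 0.0339 against 11.5 ± 0.327).

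After Txlnb and Ptbp2 the largest increases were in the perinatal skeletal myosin Myh8, Mb, Ccdc88c, the membrane repair protein Trim72, the growth factor Fgf18 and the angiogenic factor Aggf1. Igfbp5 (473 ± 4.05 against 196.5 ± 4.82) and fibromodulin Fmod completed them, and log2 fold changes ran from 2.07 for Myh8 to 1.26 for Fmod. Myosin heavy chain genes are close copies of each other, so reads of Myh8 and Myh1 are uncertain. Mb was 19.6 with shPtbp1, 7.04 with shNT and 19.9 with MGT alone. Myh8 was also lower with shNT than with MGT alone, so low values in the shNT libraries would give both increases. After Ptbp1 the largest decreases were in Slitrk4, the interleukin 1 antagonist Il1rn, the formin Fmnl3 (50.1 ± 3.48 against 125 ± 0.768), asporin Aspn and hemicentin Hmcn1, from -1.69 to -1.26. The amino acid transporter Slc38a6, the metalloproteinase inhibitor Reck, the lactate transporter Slc16a3 and the macrophage elastase Mmp12 followed, from -1.17 to -1.09.

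In the sarcomere list Tcap, Myom2 and Tnni3 rose by 0.84, 0.80 and 0.58 in log2 units, while skeletal actin Acta1 fell by 0.67. Its camera adjusted p was 1.25e-05 at the preset correlation, and adjusted p = 0.125 with an estimated correlation. The mitosis list, with Bub1, Aurkb and Cenpe lower by 0.45, 0.40 and 0.39, had 4.89e-07 and held at 0.0258. Apart from the sarcomere list, no cardiac list was called by camera. Calcium handling and ion channel genes rose in 6 of 23 and fell in 7 (adjusted p = 0.983). Cardiac transcription factors rose in 1 of 15 and fell in 3 (0.544), and other cardiomyocyte markers rose in 8 of 20 and fell in 1 (0.134). DNA replication genes fell in 11 of 20 and rose in 1, with Tyms, Mcm5 and Mcm2 lower (adjusted p = 0.00156, and 0.373 with an estimated correlation). Ribosomal protein genes rose in 25 of 30, by at most 0.22, and oxidative phosphorylation genes in 11 of 30, by at most 0.30 (2.71e-07 and 0.00156, and 0.449 and 0.547 with an estimated correlation). Myofibroblast contractile genes fell in 9 of 16, among them Cnn1, Tpm2 and Cald1 by 0.81, 0.66 and 0.56, and rose in 2. TGF-beta response genes fell in 8 of 17 and rose in 3. The adjusted p of these 2 lists were 0.0357 and 0.0306, and 0.547 and 0.449 with an estimated correlation. Macrophage markers moved beside these groups, lower in 8 of 14 and higher in 1, with Cd14 lower by 0.66 and C1qa by 0.47 (adjusted p = 0.00156, and 0.13 with an estimated correlation).

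Mef2c was 529 ± 22.7 against 473 ± 4.19 (adjusted p = 0.00344), Tbx5 was 1697 ± 82.9 against 1551 ± 13.4 (0.0521) and Gata4 was 652 ± 8.15 against 635 ± 13.4 (0.517). For Tbx5 the adjusted p ranged from 0.0169 with the replicate number as a block to 0.349 without shPtbp1 replicate 2, with 0.0217 without shPtbp1 replicate 1. The cardiomyocyte set rose in 61 genes and fell in 26 (median 0.07, adjusted p = 0.00933, and 0.134 with an estimated correlation). The fibroblast set, with 62 higher and 45 lower, was not called (0.157), but had an adjusted p of 0.0204 without shPtbp1 replicate 2. Across genes the change correlated with that of MGT against control at Pearson r = 0.229 and Spearman rho = 0.131, although these comparisons share no library. Of 2182 genes called in both, 61.2% had the same direction, with 715 higher in both where independent lists would give 418, and 620 lower in both where they would give 448. With the cardiomyocyte-to-fibroblast difference r was 0.055 and rho 0.079, and 56.8% of 3969 shared calls had the same direction.

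Over all genes, 2339 were higher and 2531 lower, or 2449 and 2397 with upper-quartile scaling, and 59 and 32 changed at least 2-fold. Adjusted over the list alone, 17 sarcomere and 28 ribosomal protein genes rose, and the other called lists kept their counts. The lower count was 1687 without shNT replicate 1, and the 2-fold counts were 158 and 103 with edgeR's quasi-likelihood test. The TGF-beta call was lost without shPtbp1 replicate 1 and without shNT replicate 1, the myofibroblast call without shPtbp1 replicate 1, and the oxidative phosphorylation call without shPtbp1 replicate 2.

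The shNT wells were compared with the MGT wells to measure what differed with the non-targeting hairpin virus, although a batch of the hairpin wells would give the same contrast. All 14 macrophage markers were lower, with a median log2 fold change of -1.70 (camera adjusted p = 1.31e-20, and 0.00269 with an estimated correlation). The mannose receptor Mrc1 was 31.8 ± 0.00751 against 252 ± 4.18, and the complement genes C1qb, C1qc and C1qa were lower by -2.56, -2.33 and -2.22 in log2 units. The largest decreases overall were in the Fc receptor Fcgr2b (5.46 ± 0.0371 against 105 ± 5.32), Il21r, the scavenger receptor Stab1 (56.8 ± 3.82 against 453 ± 8.54), Mrc1 and Cd22. The largest increases were in Smpd3, Lrrn4, the immediate-early factor Egr1 (243 ± 17.2 against 92.8 ± 4.18), the cystine transporter Slc7a11 and the collagen-binding integrin Itga11, from 1.89 to 1.16. Smpd3 and Lrrn4 were also the largest decreases of MGT against control, which uses the same MGT libraries. Smpd3 was 10.95 in control, 3.45 with MGT and 14.15 with MGT and shNT, and Lrrn4 was 21.28, 9.185 and 27.42. Low values in the MGT libraries alone would give both changes.

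Immediate-early and heat shock genes rose in 15 of 19 and fell in 2, led by Egr1 and the heat shock pair Hspa1a and Hspa1b, near-identical copies whose reads are uncertain. Inflammatory genes fell in 11 of 19 and rose in 1, with Tnf, Ccl7 and Ccl2 lower by 1.67, 1.64 and 1.08, beside the fall of the macrophage markers. Unfolded protein and integrated stress genes fell in 11 of 16 and rose in 1, with Trib3 and Sdf2l1 lower by 0.79 and 0.57. The p53 and senescence list rose in 9 of 17, led by Mdm2 (0.45) and Gdf15 (0.45). Myofibroblast contractile genes rose in 10 of 16, and 4 of 8 skeletal muscle genes fell, with Myh8, Tnni2 and Myh1 lower by 2.32, 1.31 and 1.30. These 6 lists had adjusted p of 2.14e-05, 0.00216, 0.00303, 0.00917, 0.00528 and 0.0128, and 0.338, 0.342, 0.181, 0.342, 0.462 and 0.29 with an estimated correlation. Mef2c was 473 ± 4.19 against 741 ± 29 with MGT alone, Tbx5 was 1551 against 1809 and Gata4 was 635 against 692.

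In total 3432 genes were higher and 2809 lower in the shNT wells, and 38 and 453 changed at least 2-fold. The excess of higher genes turned with edgeR's quasi-likelihood test (2978 higher, 3188 lower) and was 3782 against 2539 with quantile normalization. This comparison shares libraries with both comparisons described before it. With edgeR the 2-fold counts were 130 and 684, and Gata4 lost its call without MGT replicate 2 (adjusted p = 0.117), without shNT replicate 2 (0.13), without a filter (0.0529) and in a fit of the day 3 libraries (0.0611), where all alternatives ranged from 0.0026 to 0.13. Adjusted over the list alone, 12 unfolded protein and stress genes were lower, and the other called lists kept their counts.

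**Figure D3:**
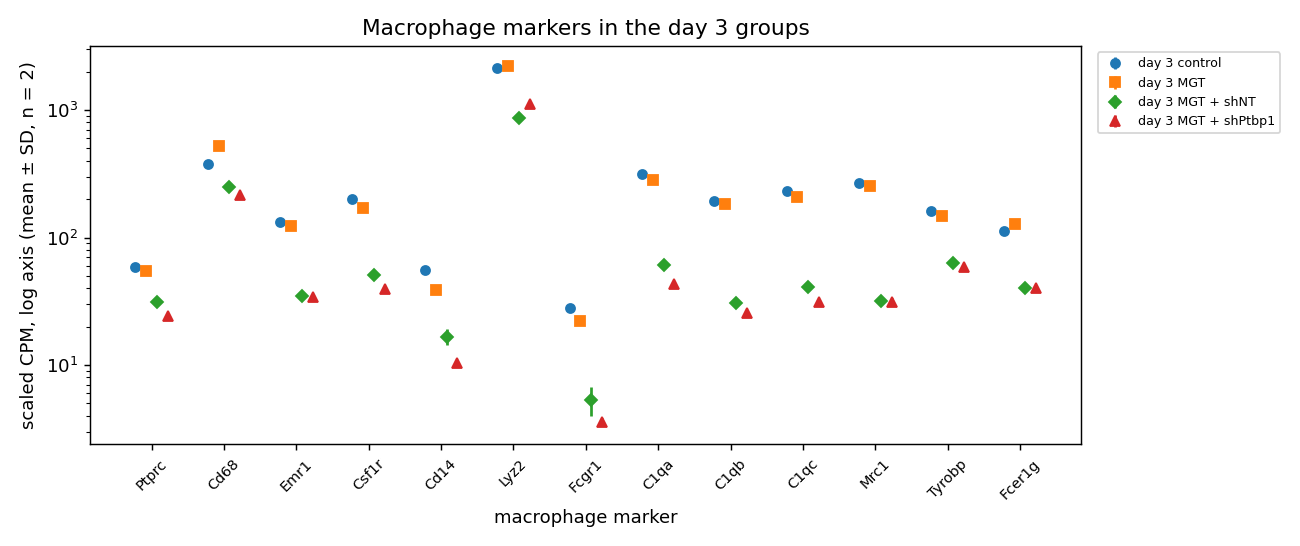
Scaled CPM (log axis; mean ± SD, n = 2) of macrophage markers in the 4 day 3 groups; Cd163, which was below 1 scaled CPM in all 4, is not drawn. Mrc1 was 252 with MGT and 31.8 with MGT and shNT.

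Control cultures were compared with fresh fibroblasts to measure the change from fresh to cultured, control-infected cells. The immediate-early and heat shock list fell in 18 of 19 genes, with a median log2 fold change of -4.07. Fosb was 1.645 ± 0.18 in culture against 971 ± 17.6, Fos 10.1 ± 0.8 against 2446 ± 13.6, and Hspa1b 9.19 ± 0.684 against 2316 ± 126. Endothelial markers fell in 14 of 14, with a median of -4.94, and the genes Cldn5, Kdr, Fabp4 and Esam fell by 7.52, 5.62, 5.43 and 5.25. Interferon response genes rose in 27 of 28, led by Ifit1, Ifit3, Isg15 and Usp18 with log2 fold changes of 5.73, 4.59, 4.53 and 4.24.

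The largest increases were in secretogranin Scg2 (235 ± 19.9 against 0.384 ± 0.0632), the lysosomal glycoprotein Gpnmb (3559 ± 98.7 against 20.1 ± 2.3), osteopontin Spp1 (1246 ± 164 against 9.42 ± 0.121), Wisp2 and Tbx5 (661 ± 23.2 against 7.23 ± 0.415). The largest decreases after Fosb, Hspa1b and Fos were in the apelin receptor Aplnr and Clec3b, with log2 fold changes of -7.73 and -7.67. Myofibroblast contractile genes rose in 13 of 16, with Tagln at 2027 against 113 and smooth muscle actin Acta2 at 5499 against 498. Glycolysis rose in 15 of 16 genes, with hexokinase Hk2 and Pgam1 up by 2.99 and 1.79. Ribosomal proteins rose in 30 of 30, oxidative phosphorylation in 29 of 30, the p53 and senescence list in 14 of 17 and the unfolded protein and stress list in 12 of 16. Splicing regulators fell in 31 of 46, with Nova2, Nova1 and Rbm24 lower by 4.73, 2.73 and 2.68, and cardiac transcription factors fell in 11 of 15. Macrophage markers rose in 11 of 14, with Lyz2 at 2143 against 162 and Cd68 at 379 against 61.8, and pericyte markers fell in 5 of 6. Some members went the other way, with 6 splicing regulators, 1 cardiac transcription factor and 1 pericyte marker higher. Lower were 3 myofibroblast, 1 glycolysis, 2 p53, 3 unfolded protein and 2 macrophage genes.

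The 13 lists called by camera were the 3 named first (adjusted p of 5.02e-09, 3.11e-08 and 3.11e-08), myofibroblast (0.000724), glycolysis (1.95e-05), ribosomal (2.84e-08), oxidative phosphorylation (1.95e-05), p53 (0.000724), unfolded protein (0.0177), splicing (0.00146), cardiac transcription factors (0.0173), macrophage (0.00334) and pericyte (0.00896). None of these lists held its call: with an estimated correlation, adjusted p = 0.121 for immediate-early, endothelial, glycolysis, splicing, macrophage and pericyte lists. It was 0.349 for interferon and oxidative phosphorylation, 0.314 for myofibroblast, 0.339 for ribosomal and cardiac transcription factor lists, and 0.143 for the p53 and unfolded protein lists. The pericyte list lost its call although its estimated correlation was -0.089, below the preset value, so these losses need not reflect correlation between genes. Sarcomere genes moved both ways, 8 higher and 17 lower, without a call (0.124). Myl4 was 894 against 27.4, while Myl2 was 4.59 against 245 and Myh7 was 5.57 against 215.

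In control cultures 6075 genes were higher and 6067 lower, of which 1680 and 2485 changed at least 2-fold. Without scaling 5398 were higher and 6682 lower, and with quantile normalization 6784 and 5433. Without a filter 6557 were higher and 7068 lower, so the direction of the excess rests on the scaling and the filter. Without library scaling the median of all genes was -0.10 in log2 units, against 0.00376 with it, and with quantile normalization it was 0.11. Adjusted over the list alone, 30 splicing regulators fell, and the other called lists kept their counts. The fresh and cultured cells also differed in virus, and no uninfected culture was analysed here.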

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

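Among 310 named gene and comparison pairs, no direction turned where the gene was called in the main fit or in the alternative. Turns of genes called in neither were not counted. Of 4805 alternative values 4755 stayed on the same side of the threshold, 39, in 12 pairs, lost a call and 11 gained one. Of 411 alternatives of the main counts, sets and correlations, 382 stayed within their limits, and the cause of the moves was not tested unless stated. The limits for counts were wide. For example, the genes lower with MGT stayed within them at 1838 instead of 2475, in the fit of only the 4 libraries compared. On recovered reads (100% whole), edgeR's quasi-likelihood test called 2578 genes higher and 2578 lower for MGT and 2448 and 2488 for shPtbp1. It called 2978 and 3188 for shNT, 4747 and 5936 for cardiomyocytes, and 6325 and 5862 for culture. The 2-fold counts depended on the pseudocount, which by construction shrinks low genes. They also differed with edgeR, whose fold changes do not use that pseudocount, so the 2 dependences may not be separate. For MGT against control they were 164 higher and 37 lower at a pseudocount of 0.1, 52 and 2 at 2, and 202 and 73 with edgeR. For Ptbp1 silencing they were 107 and 73, 21 and 12, and 158 and 103. For the non-targeting hairpin they were 90 higher at 0.1, 10 higher at 2, and 130 and 684 with edgeR, and for cardiomyocytes 327 lower at 2. With an estimated inter-gene correlation, 4 lists were called for cardiomyocytes against fibroblasts, 3 for MGT, 1 for Ptbp1 silencing, 1 for the non-targeting hairpin and 0 for culture, and the cardiomyocyte set (median 0.068) lost its call for Ptbp1 silencing (adjusted p = 0.134). The correlation of MGT with the cardiomyocyte-to-fibroblast difference was 0.063 and 0.043 at pseudocounts of 0.1 and 2, and 0.064 with a filter at 5 CPM.

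Leaving out 1 replicate at a time, where the lone sample is assumed to vary like the other groups, the genes lower ranged from 1598 to 2247 for MGT (1598 without MGT replicate 2) and from 1687 to 2325 for Ptbp1 silencing (1687 without shNT replicate 1). The fibroblast set ranged from 0.02 to 0.069 for Ptbp1 silencing and passed the threshold without shPtbp1 replicate 2. Leaving out a replicate removes a sample and lowers power. Replicate numbers are shared between groups but nothing says that they pair samples: of 15 pairs of groups, deviations of same-numbered samples correlated from -0.14 to 0.16, above 0.1 in 1, the pair of shPtbp1 and shNT (0.16). With the replicate block, 2478 genes were higher and 2421 lower for MGT and 2288 and 2472 for Ptbp1 silencing, and Tbx5 passed for silencing (adjusted p = 0.0169, where the alternatives ranged from 0.0169 to 0.349). Depth, at 49320858 reads or more, left 1 read at 0.0203 CPM or less, and the filter of 1 CPM lay well above it.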

Other observations

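All tests in this part were chosen after the results were seen, and the genes of the next 2 paragraphs were picked after their values were seen. The tests of the sarcomere and macrophage patterns were changed in form after their values were seen, and an earlier form, based on a 2-fold window around each list's own median, had favoured the explanations that a later form spoke against, so neither is decided here.

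H19, Igf2, Mest and Dlk1, known as imprinted genes, were lower in control cultures than in fresh fibroblasts, a comparison in which 6067 of 13977 genes were lower. Imprinted genes were not tested as a group. H19 was 44.1 against 4043 scaled CPM, Igf2 75.7 against 3503, Mest 44.2 against 1027 and Dlk1 6.95 against 226, with log2 fold changes of -6.51, -5.52, -4.53 and -4.93. Cdkn1c (-4.30) and Peg3 (-2.45) were lower as well. Fresh cardiomyocytes held H19 at 6121 and Igf2 at 5152. Mest was 44.2 in control, 59.6 with MGT, 129.5 with shNT and 131 with shPtbp1.

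Mb and Myh8, which encode muscle proteins, were lower with MGT and shNT than with MGT alone or with shPtbp1. Mb was 6.24 in control, 19.9 with MGT, 7.04 with MGT and shNT and 19.6 with MGT and shPtbp1, and Myh8 was 16.0, 18.0, 3.21 and 15.15 in the same order. The shNT libraries serve both contrasts, so genes low by chance in them would show the same pattern. Mmp12 was 289, 529, 173 and 80.8, and Gpnmb was 3559, 4858, 2231 and 2406.

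The excess of Tbx5 over fresh fibroblasts was 36.3% as large in control cultures as with MGT. If that came from RNA of MGT cells mixed into the control libraries, the same share would set a floor for every gene. Of 9349 genes with at least 10 scaled CPM with MGT, 9 lay below the floor by over 2 SE. Among them were Col10a1 (16.1% of the MGT level), Ccdc3 (15.5%) and Necab1 (18.1%). This argues against mixing from the MGT wells as the whole source. Mixing from the hairpin wells, which also received MGT, was not tested. Factor transcripts from virus in the control wells stay open, since the shares for Mef2c, Gata4 and Tbx5 were 30.4%, 29.4% and 36.3%, 1.23-fold apart, but no uninfected culture gives the baseline. A rise of the endogenous gene in culture was not tested.

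Sarcomere genes in fresh fibroblasts, which were sorted on Thy1, had a median of 11.1% of the cardiomyocyte level, with Myh6 at 677 against 5624. Xirp1 stood at 4.73%, the lowest among genes with at least 100 scaled CPM in cardiomyocytes, and 25 of 25 sarcomere genes lay above it by over 2 SE. Cardiomyocyte RNA at one share as the whole source stays open, since Xirp1 was picked as the most extreme gene and cardiomyocytes among the sorted cells need not match the separate cardiomyocyte preparation. No biological explanation was tested.

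Macrophage markers were lower in the shNT wells by a median of 1.70 log2 units, with Lyz2 at 866.5 against 2222. Among the 13 with at least 10 scaled CPM with MGT, the changes ran from -0.81 to -2.97, with an SD 14.1 times their median SE. A lower share of macrophage RNA stays open, as does a change in the macrophages themselves, since other cells can add to each marker and the SE rests on 2 libraries per group. A batch of the hairpin wells that the labels do not give cannot be told apart from the second virus, since the component that parts these wells (5.4% of the variance) follows both.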
